A study of Drosophila melanogaster with 2 samples.

How the data were processed

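Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 12 h. The embryos came from a transgenic line in which the CG2202 protein carries a green fluorescent protein (GFP) tag, and an antibody against GFP was used for the precipitation. Per the labels, chromatin was fragmented by sonication, with a size range of 200 to 800. The 2 samples form 1 group and are biological replicates, labelled as separate embryo collections of the same line. No second condition was analysed here, so the comparisons are between the replicates and between stronger and weaker peaks.

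The deposited files are peak lists on the dm6 assembly. Per the deposited text files, each replicate list derives from that replicate's alignment and a control alignment, the pooled list from both replicate alignments and the control, and the IDR (irreproducible discovery rate) list from both replicate lists and the pooled list. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each deposited peak carries a signal value set by the caller, which is the authors' own value. It was used to rank, describe, filter or compare peaks within 1 list, and between the replicate lists only to correlate them. Each deposited peak also carries a −log10 q-value, which reaches a single maximum per list, 4.12 in the IDR and pooled lists, and was not used for ranking. Read depths were not given in the sources used here, so depth is unknown and no interval based on reads was computed. Exact binomial (Clopper-Pearson) 95% intervals of shares cover the counting of peaks or genes only.

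All 3571 IDR peaks were also in the pooled list, and they were its 3571 peaks of highest signal. The IDR list was compared with weaker pooled peaks, defined as the 25659 pooled peaks that overlapped no IDR peak by 1 bp or more. This is a comparison of stronger with weaker peaks of the same reads, and 770 pooled peaks that overlapped an IDR peak without being one were left out. The caller's q-value was below 0.05 for 13201 of the 30000 pooled peaks, among them all 3571 IDR peaks. Most weaker pooled peaks therefore did not reach that value, and they cannot be taken as a set of weaker binding sites. All lists held peaks on chromosome arms 2L, 2R, 3L, 3R, 4 and X only. Some peaks share coordinates and differ in summit, and were kept as separate peaks. In the IDR list 15 peaks repeated the coordinates of an earlier peak.

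Genes and transcription start sites (TSSs) came from the Ensembl annotation of the Release 6 assembly, whose arm lengths match dm6, with 17896 genes and 23722 TSSs on the 6 arms. A summit within 500 bp of a TSS was called a promoter summit, and other summits were assigned in order to 5′ UTR, coding exon, 3′ UTR, other exon, intron or intergenic sequence. A gene was called bound when an IDR summit lay within 500 bp of any of its TSSs, and the background was the 8721 genes with any pooled summit there. Sequence was taken from 50 bp either side of each summit, on either strand.

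Shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family at a threshold of 0.05. Odds ratios have 95% Wald intervals. Overlap of peaks meant at least 1 bp, and chance overlap came from 1000 circular shifts of a list within chromosome arms, with 0.001 the smallest p they can give. Medians and rank correlations were tested with 100000 permutations, two-sided, with 1e-05 the smallest p they can give. Peaks and genes are not replicates of the experiment, so p-values describe these lists and not the spread between embryo collections. Composition of sequence was controlled by comparing peaks within 20 strata of GC content, using the Mantel-Haenszel odds ratio.

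The 29 gene lists, 27 consensus words, tests, alternatives and the rule for named items were fixed before the data were examined. Lists with fewer than 5 background genes were not tested. Named items are the 25 promoter and 5 distal IDR peaks of highest signal, up to 4 bound genes of highest signal per tested list, the 5 IDR peaks whose rank percentiles differed most between the replicate lists, CG2202 itself, and the 10 words and 5 8-mers of smallest p. The alternatives were a stricter list of 1000 peaks, other overlaps, other TSS windows, other backgrounds and each replicate's top 3571 peaks alone. The comparisons within GC strata of TSS proximity, annotation classes, arms, divergent promoters, gene lists and words, and the comparison of 8-mers with randomly drawn weaker peaks, were added after the data had been seen. Peaks were first explored by class, arm, gene list and 8-mers, the last also in bands of rank and against peaks matched in GC content, before the tests of explanations were written.

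The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and was tested on simulated data. A random draw of background summits gave 0 called 8-mers of 32896, and 10 of 10 8-mers planted in 1.5% of summits were recovered. A draw biased to AT-rich summits with no planted motif gave 2937 called 8-mers without control of GC content, and 0 of 2080 hexamers within GC strata. In 100 random draws of bound genes 5 lists were called, and the mitochondrial ribosomal list, when raised to 60% bound, was called in 100 of 100 draws.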

Results

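CG2202-GFP binding was profiled in whole embryos of 0 to 12 h in 2 biological replicates. The list of each replicate and the pooled list held 30000 peaks each, and the IDR list held 3571. Lists of equal size cannot be read as counts of binding sites. The caller's q-value was below 0.05 for 11103 peaks of replicate 1, 12466 of replicate 2 and 13201 of the pooled list. Overlap with a list, or a pooled summit at a gene, can therefore rest on a peak that did not reach that value. The IDR peaks covered 1.11 Mb, or 0.833% of the 6 chromosome arms, with a median width of 400 bp and signal values from 120.9 to 2324. Sequencing depth is unknown.

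Peaks were compared between the replicates to ask how far the 2 embryo collections gave the same sites. The strongest peak was the same in the pooled list and in both replicate lists, a summit 204 bp upstream of a TSS of px (plexus, FBgn0003175), which encodes a nuclear protein of wing vein patterning, at 2R 22514097 to 22514513. Of the IDR peaks, 99.1% overlapped a peak of replicate 1 (95% interval 98.7 to 99.4%) and 99.4% a peak of replicate 2 (99.1 to 99.7%), where shifted lists gave means of 14.2% and 13.9%. Weaker pooled peaks were found less often, 73.9% in replicate 1 and 72.2% in replicate 2. When each replicate was limited to its own top 3571 peaks, 65.8% of those of replicate 1 were overlapped by those of replicate 2, against a mean of 1.77% and a highest value of 2.69% in shifted lists (p = 0.001, permutation by circular shift, the smallest it can give). Of the IDR peaks, 2310 lay within the top 3571 of both replicates, 1223 within those of 1 replicate, and 38 within those of neither.

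Signal ranks were shared in part. Across the 3519 IDR peaks found in both lists, Spearman's rho was 0.399 (p = 1e-05, permutation test, the smallest it can give), computed across peaks, which are not independent replicates. It was 0.616 across the 17502 pooled peaks found in both lists, a set not limited to peaks of high signal. The 5 peaks that differed most in rank were split by direction. Peaks in introns of jing, tai and the Hox gene lab ranked 771, 1268 and 802 in replicate 1 and 29297, 29238 and 28594 in replicate 2. Promoter peaks of LamC, a lamin gene, and of the small heat shock gene Hsp22 ranked 29903 and 28804 in replicate 1 and 1376 and 1523 in replicate 2. In the replicate where they ranked low, all 5 were near the floor of the list. The signals were 16.2 to 16.5 in replicate 2, whose lowest is 15.9, and 16.4 and 16.9 in replicate 1, whose lowest is 16.3. The IDR list derives in part from the replicate lists, so overlap with them is not an independent measure of agreement.

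IDR summits lay at promoters more often than weaker summits did. Of 3571 IDR summits, 1618 were within 500 bp of a TSS, 45.3% (95% interval 43.7 to 47.0%), against 29.7% of weaker pooled summits (29.2 to 30.3%) and 13.4% of all bases. The odds ratio was 1.96 (1.82 to 2.10, Fisher's exact test, p = 1.26e-74), and the share was 42.8% for the top peaks of replicate 1 and 48.8% for those of replicate 2. Among promoter summits of the IDR list, 74.5% lay upstream of the nearest TSS (72.3 to 76.6%), with a median position of -100 bp, whereas 53.4% of weaker promoter summits did (52.3 to 54.5%), with a median of -12 bp. The promoter difference is one between strong and weak peaks in general, since the strongest 3571 weaker peaks had a share of 46.8%, which gave an odds ratio of 0.941 against them (0.857 to 1.03, Fisher's exact test, p = 0.208).

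**Figure D1:**
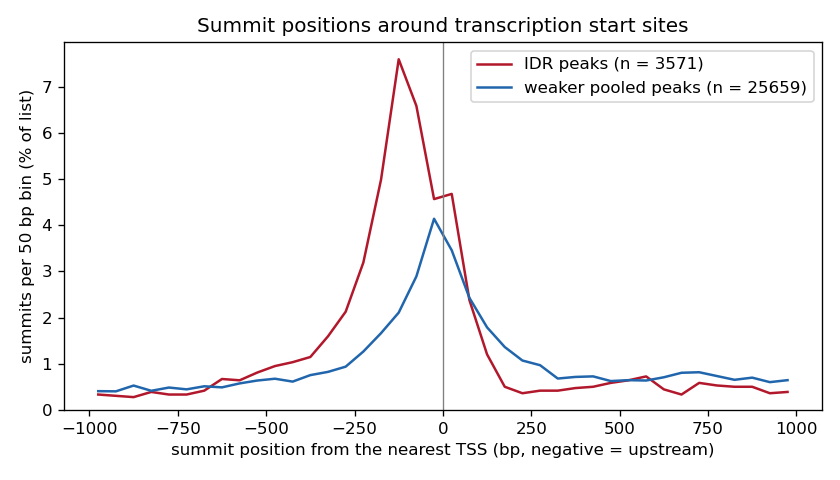
Position of summits relative to the nearest TSS (x axis, bp, negative values upstream) as a percentage of each list per 50 bp bin (y axis), for 3571 IDR peaks and 25659 weaker pooled peaks. The IDR line is highest in the bin from -150 to -100 bp, at 7.59% of peaks, where the weaker peaks reach 2.11%.

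The promoter peaks of highest signal were at genes of varied function. After px came CG14100 (signal 1991), CG1888 (1777), the noncoding RNA gene lncRNA:CR31840 (1690), ph-p (1483), which encodes a Polycomb group protein, and Art3 (1421), an arginine methyltransferase gene. They were followed by Ugalt (1404), a UDP-galactose transporter gene, lncRNA:CR44339 (1378), CG18549 (1355), Chro (1354), which encodes the chromatin protein Chromator, CG5611 (1328) and CHMP2B (1320), an ESCRT-III gene. Fkbp14 (1249), CG11309 (1237), RluA-1 (1231), CG9147 (1188), CenG1A (1165), lncRNA:CR31044 (1135), CG1635 (1127), PNPase (1118) and Tina-1 (1112) came next. The remaining ones were CG8320 (1101), a summit 173 bp upstream of both Pdrg1 and Pal1 (1027), gish (1026), a casein kinase gene, and a further peak at ph-p (1015). All 25 ranked within the top 105 of replicate 1 and the top 46 of replicate 2.

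Strong peaks away from promoters lay mostly in introns. The distal peak of highest signal, 1721, was in an intron of CG11050 at 2L 6612470 to 6612909. Intronic peaks of ush, a gene for a cofactor of GATA factors, cno, which encodes the junction protein Canoe, and sbb had signals of 1597, 1566 and 1456, and an intergenic peak 11907 bp downstream of the TSS of CG13323 had 1424. In median signal, the promoter and distal IDR peaks were not told apart, at 192.1 (quartiles 146.2 to 296.7) and 194.7 (147.7 to 275.5, permutation test, p = 0.687). The mean of log2 signal was 0.05 higher at promoters (permutation test, p = 0.0283), so the direction depended on the statistic.

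Coding exons were nearly free of IDR summits. They held 7 of 3571, 0.196%, against 6.92% of weaker summits and 13.7% of bases (odds ratio 0.0264, 0.0126 to 0.0555, Fisher's exact test, adjusted p = 1.47e-90). 3′ UTRs held 0.700% against 2.67% (odds ratio 0.257, Fisher's exact test, adjusted p = 9.03e-16), and intergenic sequence 15.8% against 19.5% (odds ratio 0.773, Fisher's exact test, adjusted p = 1.08e-07). Introns held 36.4% and 39.0% (odds ratio 0.895, Fisher's exact test, adjusted p = 0.00416), a difference that did not pass in the top peaks of replicate 1, where the odds ratio was 1.03, nor with promoters defined by 250 bp, where it was 0.979. 5′ UTRs held 0.588% and 1.09% (odds ratio 0.538, Fisher's exact test, adjusted p = 0.00512), a difference that passed neither in the top peaks of replicate 1 (0.677) nor within strata of GC content (0.773), an alternative chosen after seeing the data. The odds ratio of coding exons was 0.0709 in those strata and 0.0146 in the top peaks of replicate 2, where that of 3′ UTRs was 0.122. Other exons did not differ (1.01% and 1.07%, Fisher's exact test, adjusted p = 0.794). Against the strongest weaker peaks, where coding exons held 0.364%, 0 of the 7 classes passed after adjustment, and 1 class, 3′ UTR, had an unadjusted p under 0.05 (Fisher's exact test, p = 0.0218).

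**Figure D2:**
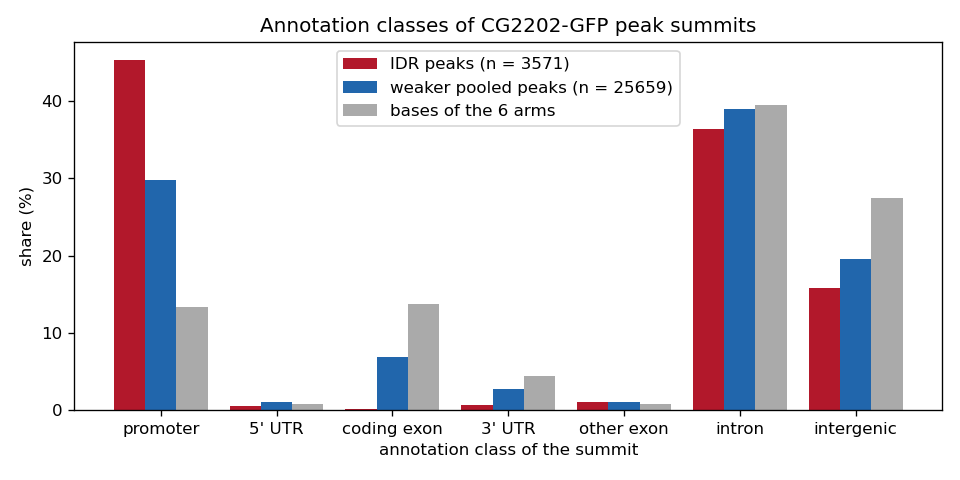
Share of summits (y axis, %) in each annotation class (x axis) for IDR peaks, weaker pooled peaks and the bases of the 6 arms. Promoters hold 45.3%, 29.7% and 13.4% and coding exons 0.196%, 6.92% and 13.7% of the 3 in turn.

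IDR promoter peaks lay near TSSs of both strands more often than weaker ones. TSSs on both strands were within 500 bp of 584 of 1618 IDR promoter summits, 36.1%, and of 1620 of 7630 weaker ones, 21.2% (odds ratio 2.10, 1.87 to 2.35, Fisher's exact test, p = 1.19e-34). The share was 30.9% for the top peaks of replicate 1 and 39.1% for those of replicate 2. Against the strongest weaker peaks the odds ratio was 1.27 (1.10 to 1.47), a smaller value that also passed (Fisher's exact test, p = 0.0013).

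IDR peaks were spread over all 6 arms. Arm 2L held 20.2% of IDR and 18.7% of weaker peaks, 2R 17.3% and 18.9%, 3L 22.3% and 22.7%, 3R 24.2% and 22.4%, the small arm 4 0.420% and 0.511%, and X 15.5% and 16.9%. After adjustment 0 of the 6 arms passed, the smallest adjusted value being 0.0530 by Fisher's exact test, and 4 arms (2L, 2R, 3R and X) had an unadjusted p under 0.05. The number of arms past the threshold was 4 against arm length (exact binomial test), 3 among promoter peaks and 2 in GC strata. X was lower and passed in all of these, with odds ratios of 0.861, 0.777 and 0.804 in turn. 3R was higher and passed among promoter peaks (1.20) and in GC strata (1.16). It passed neither against arm length (1.01) nor with the top peaks of replicate 1 (1.07) or replicate 2 (1.07). With the top peaks of replicates 1 and 2, 2L was higher (1.11 and 1.14) and 2R lower (0.876 and 0.849), and both passed. X did not pass there (0.960 and 0.952), and arm 4 passed in replicate 2 alone (0.524). In GC strata neither 2L (1.08) nor 2R (1.02) passed.

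Promoters of cytoplasmic ribosomal protein genes were bound far above the background. An IDR summit lay at 67 of the 82 with any pooled promoter summit, 81.7% (95% interval 71.6 to 89.4%), against 24.9% of all 8721 background genes (odds ratio 13.9, 7.92 to 24.4, Fisher's exact test, adjusted p = 6.88e-26). The strongest were RpS27 (signal 615.9), RpL7 (569.8), RpL34b (514.0) and RpL14 (508.4). The peaks of all 67 were within the top 3571 of replicate 1 and those of 58 within the top 3571 of replicate 2, and the median summit position was -6 bp. The size of the odds ratio depended on the list and background, at 18.3 with the top peaks of replicate 1, 6.97 with those of replicate 2, 7.51 with the top 1000 IDR peaks and 6.42 against genes with one of the strongest weaker peaks. Genes of the mitochondrial ribosome were bound at 14 of 60 (23.3%, Fisher's exact test, adjusted p = 0.949), with mRpS10 (1421, the peak it shares with Art3) and mRpS23 (1165, shared with CenG1A) the strongest. The replicates differed in direction, with 9 of 61 (14.8%, odds ratio 0.565) for the top peaks of replicate 1 and 20 of 63 (31.7%, odds ratio 1.27) for those of replicate 2.

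Transfer RNA genes were bound less often than the background. An IDR summit lay at 14 of 174, 8.05% (4.47 to 13.1%), for an odds ratio of 0.260 (0.150 to 0.449, Fisher's exact test, adjusted p = 1.85e-07). The strongest were tRNA:Tyr-GTA-1-8 (829.8) and tRNA:Gln-TTG-2-1 (405.0). Some bound tRNA genes share a peak, and tRNA:Phe-GAA-1-2 (295.9) is counted through a peak 5 bp from the TSS of RpL17. The test and the interval take genes as independent, which genes sharing a summit are not. With the top 1000 IDR peaks, at 4 of 174 genes, the odds ratio was much the same, 0.275, but did not pass (Fisher's exact test, adjusted p = 0.0524).

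No other list of the 28 tested passed after adjustment. Glycolysis genes were bound at 6 of 11 (54.5%), among them Gapdh2 (710.6), Eno (610.0), Ldh (553.1) and Hex-A (447.3), insulator and architectural protein genes at 8 of 16, among them Chro, Cp190 (764.9), Dref (310.0, the peak counted for RpL13, 6 bp from its TSS) and M1BP (301.4), and Polycomb and trithorax group genes at 8 of 17 (47.1%), among them ph-p, E(z) (530.5), brm (497.1) and Su(z)12 (147.5). Each of these 3 had an adjusted p of 0.218 by Fisher's exact test, and each passed in the top peaks of replicate 1 alone, which gave 5 lists, but not in those of replicate 2, which gave 3. Translation factor genes were bound at 15 of 40 (37.5%, Fisher's exact test, adjusted p = 0.274), with eIF4EHP (917.8), eIF6 (584.8) and eEF1gamma (483.0) the strongest. In GC strata this list passed, with an odds ratio of 2.95 (1.54 to 5.64), but without strata the odds ratio was 1.82, and 2.15 and 1.05 with the top peaks of replicates 1 and 2.

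No developmental gene list passed. Dorsoventral and mesoderm genes were bound at 5 of 16, with the heart gene tin (565.0) and vnd (242.0) the strongest, the Notch pathway and E(spl) complex at 5 of 17, with E(spl)m7-HLH (673.1) and E(spl)mdelta-HLH (418.8), neurogenic transcription factor genes and elav, a gene for a neuronal RNA-binding protein, at 3 of 15, with elav at 905.7, and segmentation genes at 3 of 19, with bcd (155.2), wg (129.8) and cad (126.2). None of the 3 segmentation gene peaks was within the top 3571 of replicate 2, whose top peaks bound 0 of 13. With the top peaks of replicates 1 and 2, the share was 38.9% and 46.7% for the Notch list and 31.3% and 18.2% for the neurogenic list. For the Notch list the direction depended on the TSS window. It was bound at 1 of 13 with 250 bp (odds ratio 0.264) and at 10 of 19 with 1000 bp (3.13), and neither passed after adjustment. The 5 Hox genes in the background had 0 bound, as had 7 dosage compensation, 5 cuticle protein and 12 chemoreceptor genes, for which counts this small allow shares of up to 52.2%, 41.0%, 52.2% and 26.5%. The smallest adjusted p of these lists was 0.218, for chemoreceptors (Fisher's exact test), which passed with the top peaks of replicate 2, at 0 of 20 (Fisher's exact test, adjusted p = 0.0336).

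The remaining lists did not pass either, with a smallest adjusted p of 0.321 by Fisher's exact test, for snRNA and snoRNA genes. Bound genes numbered 16 of 50 for the general transcription machinery, with MED27 (379.4) and Polr2B (342.0), 13 of 59 for oxidative phosphorylation, with ND-ASHI (279.2), 7 of 23 for splicing factors, with U2af50 (366.9), 6 of 30 for cell cycle and DNA replication, with dup (233.3), and 5 of 27 for aminoacyl-tRNA synthetases, with SerRS (326.2). They were 3 of 28 for proteasome subunits (10.7%, 2.27 to 28.2%), with Rpn3 (231.3), 6 of 16 for heat shock proteins, with Hsp27 (611.1) and Hsp83 (550.1), 16 of 93 for snRNA and snoRNA genes, and 6 of 23 for the Rab list, with Rab3GAP1 (265.8), which encodes a Rab regulator, and Rab5 (224.9). Of the smaller lists, 3 of 7 muscle structural genes, with sls (351.2), 2 of 8 germline genes, bgcn (193.0) and piwi (170.2), 2 of 6 synaptic genes, Rop (131.7) and Syx1A (130.7), and 1 of 9 antimicrobial peptide and PGRP genes, Drsl6 (164.4), were bound. Several of these shares differed between the top peaks of replicates 1 and 2. They were 11.1% and 27.1% for oxidative phosphorylation, 7.14% and 20.7% for the proteasome, 12.5% and 44.4% for germline genes, 21.3% and 32.7% for the general transcription machinery, 22.2% and 14.5% for snRNA and snoRNA genes, 28.6% and 21.7% for the Rab list and 12.5% and 0 for antimicrobial genes. The shares for aminoacyl-tRNA synthetases were 3 of 25 and 8 of 27, and those for heat shock proteins 7 of 14 and 7 of 15. Replication-dependent histone genes had 0 members in the background and were not tested.

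**Figure D3:**
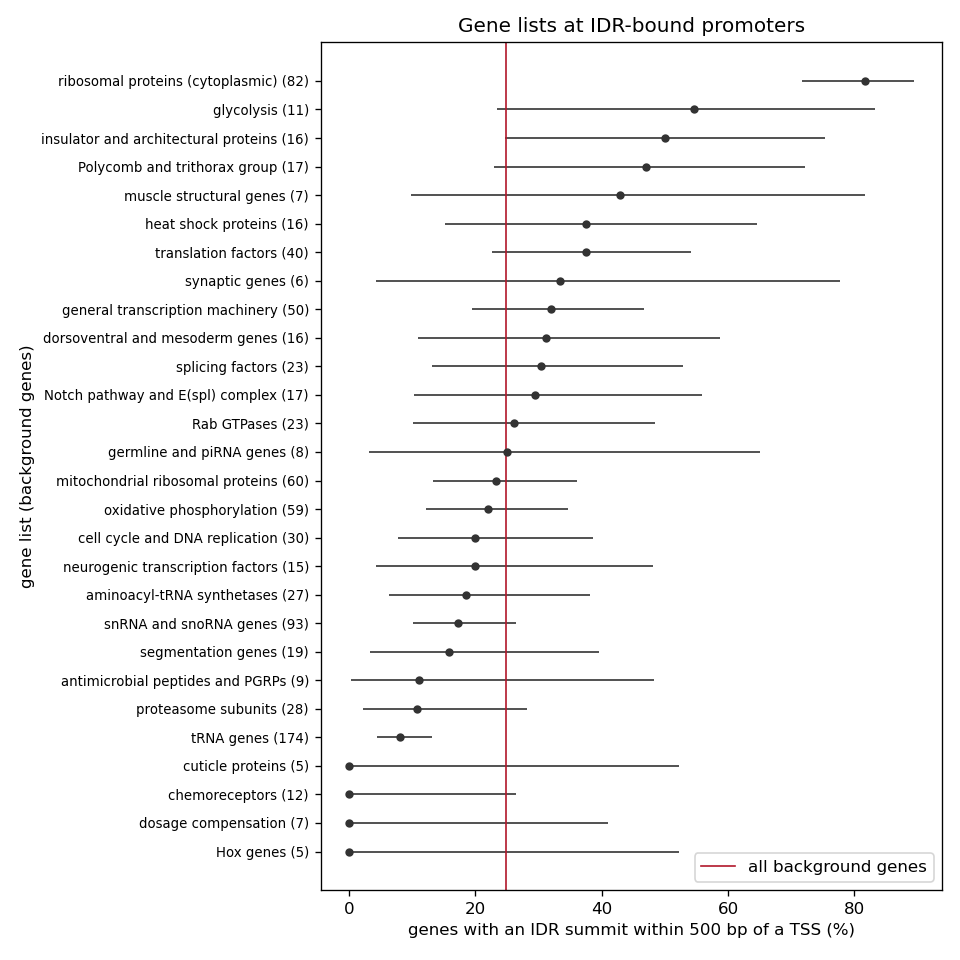
Share of background genes with an IDR summit within 500 bp of a TSS (x axis, %) for each tested list (y axis, background genes in brackets), with exact 95% intervals and the share of all background genes, 24.9%, as a line. Ribosomal protein genes stand at 81.7% and tRNA genes at 8.05%.

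IDR summits were AT-rich. Mean GC content within 50 bp of the summit was 33.7% in IDR peaks (SD 9.47 across 3571 peaks) and 41.9% in weaker peaks (SD 10.01), against 42.2% for the 6 arms, and 500 bp away it was 43.1% and 42.2%. The replicates differed, with 37.2% for the top peaks of replicate 1 and 31.4% for those of replicate 2. Of 32896 8-mers, 1453 passed after adjustment, 1064 of them more frequent at IDR summits. The smallest p values belonged to TTTAAAAA (6.30% against 2.60%), TTAAAAAA (5.88% against 2.39%), TTAAATAA (5.10% against 1.92%), ATTTAATA (4.34% against 1.504%) and AAATTAAA (6.52% against 2.89%). Against 6154 weaker peaks matched in GC content 0 8-mers passed, the smallest adjusted value being 0.0860 by Fisher's exact test, and the odds ratio of TTTAAAAA went from 2.52 to 1.14. Against 6154 weaker peaks drawn at random, an alternative chosen after seeing the data, 857 passed and that odds ratio was 2.46. Against the strongest weaker peaks 26 passed, 22 of them more frequent at IDR summits, and TTTAAAAA, with an odds ratio of 1.44, did not.

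**Figure D4:**
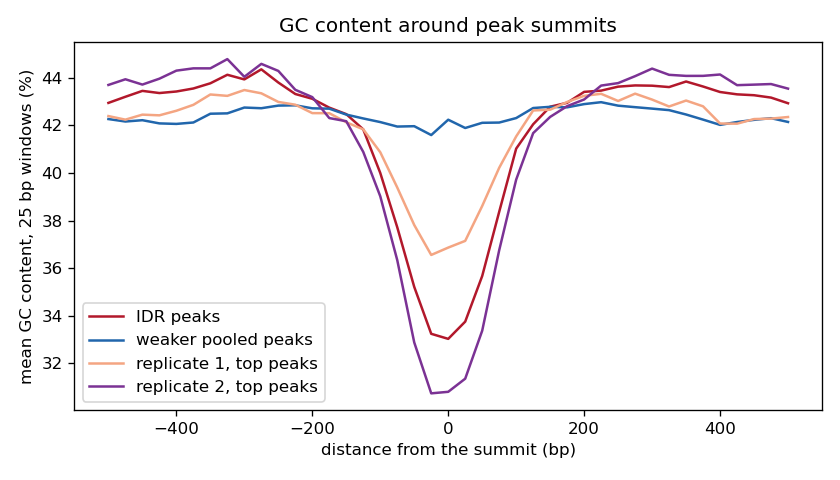
Mean GC content (y axis, %, windows of 25 bp) by distance from the summit (x axis, bp) for IDR peaks, weaker pooled peaks and the top 3571 peaks of each replicate. At the summit IDR peaks stand at 33.0% and weaker peaks at 42.2%, with 36.9% in replicate 1 and 30.8% in replicate 2.

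Of the 27 consensus words 10 passed, and of these only the forkhead word passed in the same direction within GC strata. The TATA box word (TATAAA) was in 22.5% of IDR and 12.7% of weaker summit windows (odds ratio 2.00, 1.84 to 2.18, Fisher's exact test, adjusted p = 1.36e-49), but in GC strata, an alternative chosen after seeing the data, the odds ratio was 0.944 (0.857 to 1.04). The homeodomain word (TAATTA, 9.97% against 6.22%) went from an odds ratio of 1.67 to 0.930 in the same strata, and neither word passed there. The A tract (6.50% against 5.26%) went from 1.25 to 0.702 (0.603 to 0.817), a call in the opposite direction, as with matched GC (0.740). The forkhead word (TGTTTAC, 5.26% against 3.23%) had an odds ratio of 1.66 (Fisher's exact test, adjusted p = 3.79e-08) and 1.64 in GC strata (1.39 to 1.93), but 0.902 among promoter peaks alone and 1.05 against the strongest weaker peaks, where it did not pass. Without GC strata it passed with the top peaks of replicate 1 (2.28) and of replicate 2 (1.41). In GC strata the hexamers within it, GTAAAC and TAAACA, passed in replicate 1 (1.63 and 1.53) but not in replicate 2 (1.19 and 1.08). Lower at IDR summits were the CA repeat (1.79% against 3.23%), the Twist E-box (3.50% against 5.33%), the E-box CAGCTG (3.44% against 5.14%), the GAGA factor word (1.26% against 2.05%), the Initiator (8.54% against 9.89%) and the E-box CACGTG (0.728% against 1.18%). None of these 6 passed in GC strata, where their odds ratios ran from 0.835 to 1.13. With the top peaks of replicate 1 only CAGCTG passed, and the CA repeat and GAGA words had odds ratios of 0.913 and 0.929 there, against 0.547 and 0.611 in the IDR list.

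The gene of the tagged protein was examined last. CG2202 (FBgn0030240, X 10848757 to 10852327, plus strand) had an IDR peak at its promoter, X 10848498 to 10848897, with the summit 59 bp upstream of its TSS. Its signal of 125.5 ranked 3386 in the pooled list, and the overlapping peaks ranked 5249 in replicate 1 and 2458 in replicate 2. An extra transgene copy of the locus can raise signal there when the control lacks it, which cannot be told apart from binding here. Within 20 kb of the gene were 11 pooled and 2 IDR peaks, where windows of the same size around 13944 other protein-coding genes had medians of 12 and 1. The pooled count was at or above that of 46.7% of these genes and the IDR count at or above that of 76.4%.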

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

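Replicate agreement, TSS proximity, divergent promoters and the ribosomal protein list kept their direction and their side of the threshold under the alternatives run, except as given here, and the cause was not tested unless stated. The GC strata were chosen after seeing the data. The share of IDR peaks found in both replicates, 98.5%, was 99.3% for the top 1000, 91.7% for summits within 100 bp and 73.2% for a reciprocal overlap of 50%, which asks for more by construction. Against the strongest weaker peaks the promoter odds ratio was 0.941, the intron odds ratio 1.09, 0 annotation classes passed and 26 8-mers did; that background lies next to the IDR list in signal by construction. With each replicate's top peaks alone the intron odds ratio ran from 0.796 to 1.03, the promoter minus distal signal from -1.99 to 1.44, against -2.62 in the IDR list, and the numbers past the threshold from 2 to 3 arms, 3 to 5 gene lists and 4 to 10 words. The difference in mean log2 signal was 0.0534. Arms past the threshold numbered 4 against arm length, 3 for promoter peaks and 2 in GC strata. Gene lists numbered 1 for the top 1000 peaks and 11 against all annotated genes, a background that includes genes with no pooled peak. Words past the threshold were 16 against flanks of the same peaks, 3 with matched GC and 5 in GC strata. The 8-mers numbered 366 for the top 1000 peaks, 348 for promoter peaks, both with fewer peaks tested, 2845 with 100 bp windows 0 with matched GC and 857 with as many weaker peaks drawn at random, a comparison chosen after seeing the data. Odds ratios turned for the TATA box (0.963 with matched GC, 0.944 in GC strata), the homeodomain word (0.947 and 0.930), the A tract (0.740 and 0.702) and the E-box CAGCTG (1.13 and 1.11), for the CA repeat (1.04 with matched GC), for GAGA (1.06 with 100 bp windows, 1.13 in GC strata) and for the forkhead word (0.902 at promoters). The share of other genes with no more pooled peaks than CG2202 was 70.4% for 10 kb and 63.4% for 50 kb, with 91.1% and 77.5% for IDR peaks, and by the strongest signal in 20 kb the share at or below it was 44.4%. For single classes, lists, words, 8-mers and peaks, 350 other values kept their side and 64 no longer passed or left the top 3571. The alternative with all chromosomes and scaffolds could not change anything, because the lists hold the 6 arms only. Unknown depth leaves open how much of the difference between replicates is sampling. No paired analysis was possible because there is 1 group.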

Other observations

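The comparison with GC-matched peaks was planned before the data were examined, while the other tests of explanations, the GC strata, the random draw, the hexamers by peak class, the transposable elements and the counts per intron and gene were chosen after seeing the data. Among intronic IDR summits 884 of 1300, 68%, lay in an intron that is the first of some transcript, against 60.7% of weaker intronic summits and 41.8% of intronic bases (odds ratio 1.38, 1.22 to 1.56, Fisher's exact test, p = 2.52e-07). Genes with the most IDR summits in the gene body were kirre (16 in 394.1 kb), which encodes a cell adhesion protein of myoblast fusion, CG1677 (15 in 124.7 kb), and jing, pnt and shn with 11 each, the last 3 being genes of transcription factors. Among genes with at least 8, the density was highest in CHES-1-like, a forkhead family gene, with 8 in 27.05 kb. Annotated transposable elements, 5.93% of bases, held 5 IDR summits (0.140%) and 0.316% of weaker ones (odds ratio 0.443, 0.179 to 1.09, Fisher's exact test, p = 0.0700), and in GC strata the odds ratio was 0.343 (0.139 to 0.846). Both lists were far below the share of bases, so a low share is not particular to IDR peaks. Both odds ratios rest on 5 IDR summits, and the cause was not tested.

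Within GC strata, 3 words passed that had not passed in the main comparison of IDR with weaker peaks. The CTCF word was in 1.06% of IDR and 0.861% of weaker windows, with an odds ratio of 2.49 (1.75 to 3.54) in GC strata and 2.35 (1.44 to 3.84) with matched GC. The ZIPIC word had 2.00 (1.20 to 3.34) and Ohler motif 7 had 1.45 (1.21 to 1.73) in GC strata, and with matched GC their odds ratios of 2.45 and 1.32 did not pass after adjustment. Within GC strata IDR summits still lay at promoters more often (odds ratio 2.00, 1.86 to 2.16). The values of these words were not separated from that difference. Against the strongest weaker peaks, without control of GC content, the odds ratios of CTCF (0.773) and ZIPIC (0.546) did not pass, and that of Ohler motif 7 was lower than 1 and passed (0.737, 0.596 to 0.913). Against flanks of the same peaks, also without such control, CTCF (2.47), ZIPIC (5.69) and Ohler motif 7 (1.51) all passed. With windows of 100 bp ZIPIC (2.06) and Ohler motif 7 (1.34) passed, and CTCF (1.13) did not. Of 2080 hexamers, 48 passed in GC strata (29 higher and 19 lower), with 142 for the top peaks of replicate 1 and 21 for those of replicate 2. The 4 of smallest p, CAAACA, GTCAAC, CAAATA and TAAACA, had odds ratios of 1.41, 1.67, 1.27 and 1.28, and all 4 passed in replicate 1 and none in replicate 2.

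The first pattern is the AT-rich 8-mers at IDR summits. Base composition of the summit window was tested as an explanation. Against weaker peaks matched in GC content 0 remained, a value seen before its prediction was written, whereas 857 remained against as many weaker peaks drawn at random. The loss was largely built in, because matching used the same window that holds the 8-mers. It therefore cannot tell base composition from a preference for AT-rich motifs. A GC bias of whole fragments was predicted to lower GC content 100 bp away as well. For the IDR list the deficit there was 0.186 of that at the summit (95% bootstrap interval 0.147 to 0.221), smaller than predicted. This does not exclude such a bias, because summits in AT-rich fragments can also centre on their most AT-rich stretch. The top peaks of replicates 1 and 2 also differed in GC content at the summit (37.2% and 31.4%). GC content at the summit and 500 bp away was known when this test was set. Apart from the AT-rich 8-mers, a sequence preference beyond GC content is a hypothesis. Of the 29 hexamers more frequent in IDR peaks within GC strata, 5 were so in the top peaks of both replicates. They were CGCTAG, CCGGAA, TATTGA, ACAGTG and GTACAC, with odds ratios of 1.29 to 1.95. The test was set up after the matched 8-mers had given 0, and the IDR list shares reads with each replicate list. Only TATTGA of the 5 is mostly A and T, so the others do not account for AT-rich 8-mers. Among promoter and distal peaks tested apart, with fewer peaks each, the odds ratios were 1.75 and 1.76 for CGCTAG, 1.29 and 1.27 for ACAGTG, 1.25 and 1.35 for TATTGA, 1.13 and 1.52 for GTACAC, and 2.85 and 0.815 for CCGGAA, of which CCGGAA at promoters and TATTGA and GTACAC at distal peaks passed after adjustment.

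The second pattern is the ribosomal protein gene promoters in the IDR list. The odds ratio was 19.97 within strata of GC content of the promoter peak (11.2 to 35.8) and 14.1 within strata of the number of annotated TSSs per gene (7.91 to 25.1), which argues against either as the cause. Signal that any precipitation gives at very active genes stays open, since no precipitation without the tagged protein and no expression values were analysed here. The design has 1 group, and no biological explanation was tested.

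The third pattern is the few IDR summits in coding exons. GC content of the summit window is argued against as the whole cause, since the odds ratio within GC strata was 0.0709 (0.0331 to 0.152), though it was 0.0264 without strata. Against the strongest weaker peaks, which held 0.364% in coding exons, the odds ratio was 0.538 (0.214 to 1.35) and did not pass. The difference thus arises mainly from weaker peaks of lower signal. Open chromatin, which was not measured here, stays open, and no biological explanation was tested.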
